A study of Mus musculus with 18 samples.

How the data were processed

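The series measured bulk RNA from the cortex of mice in 4 groups: controls given saline (4 mice), controls given lipopolysaccharide (LPS, a component of bacterial outer membranes that sets off an innate immune response; 5 mice), mice with an astrocyte-specific conditional knockout (cKO) of Chd8 given saline (4 mice) and cKO mice given LPS (5 mice). Per the labels' protocols, LPS was given into the abdominal cavity at 5 mg/kg, tissue was taken 72 hours later, and libraries were made from ribosome-depleted total RNA with a stranded kit. The titles of all libraries carry the word for saline, so groups were taken from the genotype label, which the treatment label matches. The labels name no batch; the sample codes in the titles are plain numbers for saline libraries and letters with numbers for LPS libraries, so whether all were prepared together is unknown, and treatment and any such difference cannot be told apart.

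The analysed data are 3 tables of the authors' own comparisons, each with the same 13784 genes, of which 757 carry no symbol. Per the submitters' processing notes, cutadapt 3.5, STAR, RSEM and edgeR 3.30.3 were used with genome build GRCm39; the notes as used here give neither the role nor the order of these tools, and the gene filter is not given in the sources used here. Per the file headers, the authors deposited for each gene a log2 fold change, a mean log2 CPM over the libraries compared, an F statistic (a score with no upper limit), a p-value and an FDR. Recomputing the Benjamini-Hochberg adjustment from the deposited p-values gave the deposited FDR to within rounding. The denominator degrees of freedom implied by F and p were 8.66 for the comparison of genotypes after LPS, 9.76 for LPS in cKO and 9.85 for LPS in controls, so the authors' deposited tables come from separate fits. Values per library were not used here: the depth of each library is unknown, no library could be left out, no other split of the mice could be drawn and no spread between mice could be computed.

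The headers do not state the direction of the fold changes. Group levels were therefore back-calculated from each deposited fold change, the mean log2 CPM and the group sizes, and compared where a group stands in 2 tables. With the fold changes read as cKO minus control and as LPS minus saline, the levels from different tables differed by an SD over genes of 0.0503 in the cKO LPS group and 0.0537 in the control LPS group. With any sign turned, at least 1 of these SDs was 0.222 or more. These levels are estimates that assume libraries of equal weight.

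A gene counts as changed at an FDR below 0.05 in the authors' deposited table. Standard errors are the absolute log2 fold change divided by the root of F, so they are derived from the deposited values. The difference between the LPS responses of the genotypes was tested per gene as the difference of the log2 fold changes over its standard error, with each standard error taken from the normal quantile of the deposited p-value, and adjusted by Benjamini-Hochberg over 13784 genes; the underlying comparisons share no library. Standard errors from the normal quantile are larger than those from F, most of all for genes with small p-values. For the endothelial gene Vwf, that of the difference was 0.599, against 0.096 in controls and 0.283 in cKO mice from F. The test is therefore cautious for genes that respond strongly to LPS, as are the list tests of the difference that use it. The cKO-minus-control difference after saline was computed as a point estimate from the 3 fold changes, with no test. On simulated tables for the difference of LPS responses (13784 genes, 200 of them changed, 20 runs), this test recovered 27.8% of genes changed by 0.5 on the log2 scale, 76.0% of those changed by 1 and 95.4% of those changed by 2, and 3.37% of its calls were unchanged genes.

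Before the data were examined, 36 gene lists, the tests, the thresholds and the rule for naming genes were fixed. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed z values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The minimum of 3 measured members, set after the tables were opened, left 30 lists. An estimated inter-gene correlation needs values per library, so a preset 0.05 was tried in its place. In simulated z values with lists of at least 10 genes, 74% of lists shifted by 1 SD and 0.31% of unshifted lists were called over 50 runs. The simulated genes were independent, so these rates do not cover lists whose members vary together, nor lists of fewer than 10 genes. For every list call past the threshold, the list's median and the test had the same sign. A further 4 lists were chosen after the values were seen.

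Named genes are Chd8, the 10 largest rises and 10 largest falls per comparison among changed genes with a symbol that is not a predicted-gene, clone or pseudogene name and a mean log2 CPM of at least 0, up to 4 members with the smallest p-value per described list, and the 5 smallest p-values for the difference of LPS responses. Symbols beginning with LOC were treated as predicted genes. The values of 1 gene that this rule names are not reported here; it stays in every test and count. Genes named outside this rule are said to have been chosen after their values were seen.

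The reference annotation at hand, GENCODE M21 on an older build, was used only for gene names, overlapping genes, and the length and GC content of the longest transcript; 13730 of 13784 gene IDs matched it, and 182 symbols differed. No coordinates are given, because the builds differ. Alternatives comprised other FDR thresholds, a minimum fold change of 1.5, Holm adjustment, a minimum mean log2 CPM of 1, other standard errors, other list tests and 10000 random lists matched on mean expression. After the data were seen, a version was added in which fold changes were corrected for a cubic trend on GC content and transcript length. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.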

Results

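RNA from the cortex of 18 mice was compared between controls and mice lacking Chd8, a chromatin remodeller of the CHD family, in astrocytes. The groups held 4 control and 4 cKO mice given saline, and 5 control and 5 cKO mice killed 72 hours after LPS at 5 mg/kg. The values are those of the authors' deposited tables of 3 comparisons, and the depth of each library is unknown. The series was designed to look for expression changes caused by loss of Chd8 in astrocytes at baseline and during neuroinflammation.

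Chd8 itself was measured in whole cortex, where astrocytes are a fraction of the cells. In the authors' deposited tables, Chd8 differed little between cKO and control mice after LPS (log2 fold change 0.02 ± 0.05 SE, FDR = 0.901). It rose after LPS in controls by 0.34 ± 0.08 (FDR = 0.0312) and in cKO mice by 0.45 ± 0.07 (FDR = 0.00597) in the authors' deposited tables; the call in controls ended with the GC and length trend removed, at 0.28. The estimated difference between cKO and control mice after saline, computed from the authors' deposited tables without a test, was -0.09, at the 14.1th percentile of all genes. The remaining CHD family list of 8 genes did not pass its test for LPS in controls (adjusted p = 0.0709) or in cKO mice (adjusted p = 0.563). In controls 7 of these 8 genes lay above 0 (median 0.11), and the list passed in the rank-based test (adjusted p = 0.0439). It had an adjusted p = 0.496 with the GC and length trend removed. These whole-tissue values neither show nor exclude the loss of Chd8 in astrocytes.

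After LPS, complement, interferon, reactive astrocyte, activated microglia and endothelial genes rose in control cortex and cholesterol synthesis genes fell. In the authors' deposited table for controls, 890 genes rose and 456 fell. With a minimum fold change of 1.5 the split was 457 and 41. Among the largest rises were C3, the central complement component (3.02 ± 0.31), Pirb, a paired immunoglobulin-like receptor (3.66 ± 0.44), Cybb, the catalytic subunit of the phagocyte NADPH oxidase (2.47 ± 0.31), and Cd52 (2.43 ± 0.17), Fcgr2b (2.40 ± 0.22) and Fyb (2.37 ± 0.29). Saa3, an acute-phase protein, and Lcn2, an iron-binding secreted protein of reactive astrocytes, also rose in the authors' deposited table (FDR = 0.000108 and FDR = 0.000273); their back-calculated levels in control saline were near the floor (log2 CPM -7.1 and -7.2), so no size is given. The Y-linked genes Ddx3y and Uty stood among the rises too (FDR = 0.0351 and FDR = 0.0377), with back-calculated log2 CPM of -7.2 and -7.3 in control saline against 4.2 and 3.2 in control LPS, 5.9 and 4.8 in cKO saline, and 5.7 and 4.2 in cKO LPS. The sex of the mice is not given in the labels used here, so in the control comparison Y-linked expression differed together with treatment. Saline and LPS libraries also carry sample codes of different form in the labels, and no batch is named.

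In the authors' deposited table for controls, Rny3, a Y RNA, fell by 2.44 ± 0.17, Fam177a by 1.5 ± 0.19 and Bcas1, a gene of newly forming oligodendrocytes, by 1.05 ± 0.17. Scand1 fell by 0.99 ± 0.19 in the authors' deposited table, a call that ended with the GC and length trend removed (-0.68), as did that of the histone gene H4f16, whose fold change moved little (-1.06 and -0.99). The other 6 of the 10 largest falls were the histone genes Hist1h4m, H4f16, H4c9, H2ac19, Hist1h4n and H4c2, between -1.18 and -0.85; members of this family are near-identical, so reads can be split among them.

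Gene groups fixed beforehand moved together in controls. Some lists share members, so their results are not separate. Of the A1-type genes, C3 and Serping1 are also in the complement list, and Gbp2 is in the interferon list. H2-D1 and H2-T23 are also in the MHC class I list. The cells that gave these transcripts in whole cortex were not determined. Of 12 measured complement genes, 11 rose and none fell in the authors' deposited table, including C4b (1.91 ± 0.14), C3ar1 (1.94 ± 0.18) and C1qa (1.32 ± 0.12); the list passed with an adjusted p = 2.68e-14, and 11 members passed when adjusted over the list alone. Of 16 activated microglia genes, 11 rose, among them Lyz2 (2.37 ± 0.17) and the protease gene Ctss (1.19 ± 0.08) in the authors' deposited table (adjusted p = 1.01e-10; 15 when adjusted over the list alone). Of 12 A1-type reactive astrocyte genes, 9 rose (adjusted p = 1.01e-07; 11 when adjusted over the list alone), and of 10 pan-reactive astrocyte genes 6 rose (adjusted p = 1.76e-05; 6 when adjusted over the list alone). The latter include the intermediate filament genes Vim (1.5 ± 0.08) and Gfap (1.35 ± 0.12) and the protease inhibitor gene Serpina3n (1.78 ± 0.29) in the authors' deposited table. Of 16 interferon response genes 9 rose (adjusted p = 1.14e-07; 12 when adjusted over the list alone), led by Ifitm3 (1.5 ± 0.15) in the authors' deposited table, and of 13 MHC class I and antigen processing genes 7 rose (adjusted p = 1.77e-07; 11 when adjusted over the list alone), including B2m (0.74 ± 0.07).

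Vascular and stromal lists rose as well. Of 16 endothelial genes, 12 rose and 1 fell in the authors' deposited table, with Vwf at 2.08 ± 0.10 and Pecam1 at 1.04 ± 0.08 (adjusted p = 3.30e-11; 15 when adjusted over the list alone). Of 12 fibroblast and meninges genes 8 rose, including the collagen gene Col1a1 (1.51 ± 0.19) in the authors' deposited table (adjusted p = 1.14e-07; 10 when adjusted over the list alone). Cholesterol synthesis was the list that fell: 11 of 17 genes fell and none rose in the authors' deposited table, with Msmo1 at -0.78 ± 0.09 and Hmgcs1 at -0.54 ± 0.06 (adjusted p = 1.01e-10; 12 when adjusted over the list alone). Homeostatic astrocyte genes were mixed, with 4 of 20 higher and 4 lower past the threshold in the authors' deposited table (adjusted p = 0.610; 11 when adjusted over the list alone). Of 14 homeostatic microglia genes, 6 rose and 1 fell (adjusted p = 0.00536; 10 when adjusted over the list alone). In all, 14 of 30 lists passed upwards and 1 downwards. The calls of the A2-type reactive astrocyte list and the cytokine and chemokine list (adjusted p = 0.0274 and adjusted p = 0.0321) ended at a preset correlation of 0.05, at an adjusted p = 0.050 for each. The cytokine and chemokine call also ended in the rank-based test (adjusted p = 0.222) and among genes with a mean log2 CPM of at least 1 (adjusted p = 0.259). Excitatory neuron genes did not pass (adjusted p = 0.0513), but passed in the rank-based test (adjusted p = 0.0439) and among genes with a mean log2 CPM of at least 1 (adjusted p = 0.0482). All 4 measured choroid plexus genes lay below 0 in controls, and the list did not pass (median -0.93, adjusted p = 0.0850). The thyroid hormone carrier gene Ttr had the lowest value of these, at -4.03 ± 1.96 (FDR = 0.206) in the authors' deposited table, with a back-calculated log2 CPM of 6.7 in control saline and 2.3 in control LPS.

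**Figure D1:**
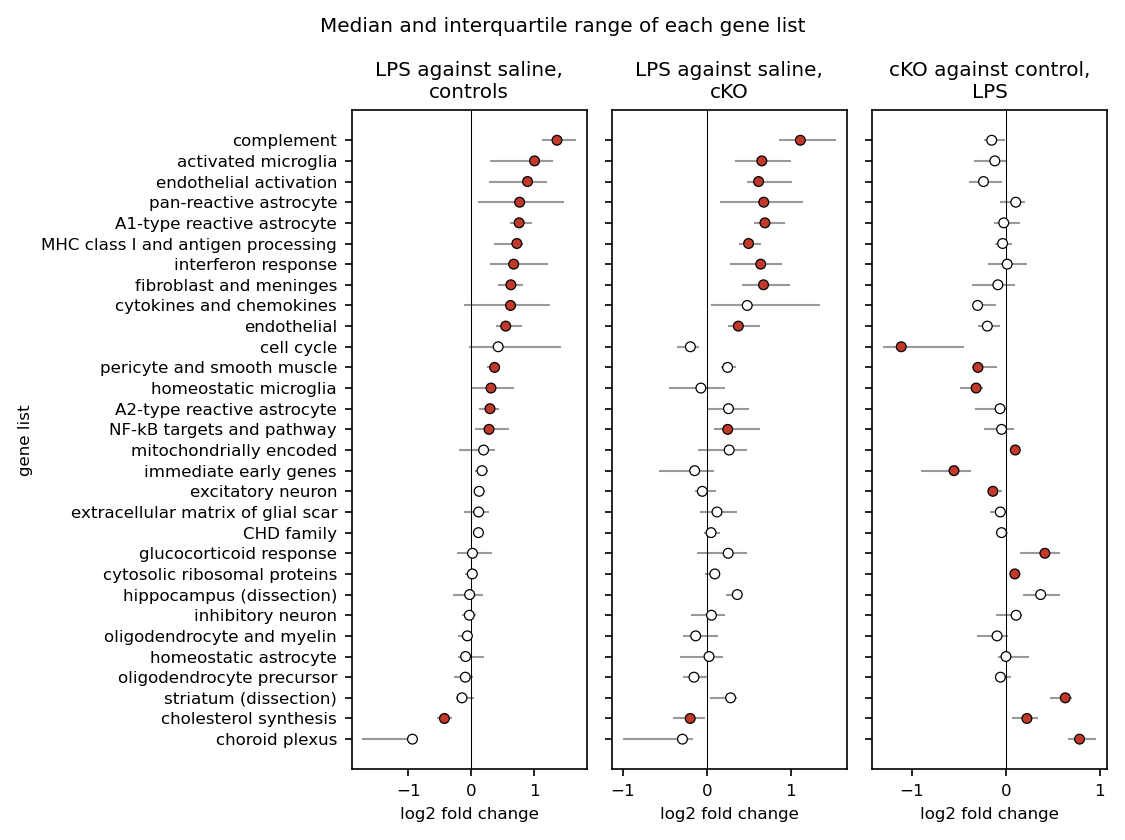
Median log2 fold change (points) and interquartile range over members (lines) of the 30 tested gene lists in the 3 comparisons; filled red points mark lists with an adjusted p below 0.05. Complement has the highest median in controls (1.36) and cKO mice (1.12), while its median for cKO against control after LPS is -0.15.

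LPS in cKO mice raised many of the same kinds of genes. Among genes in cKO mice, 1506 rose and 1175 fell in the authors' deposited table. The split was 1364 and 726 with the GC and length trend removed, and 556 and 93 with a minimum fold change of 1.5. C3 rose by 3.73 ± 0.86, Pirb by 3.22 ± 0.64, Cybb by 2.59 ± 0.51, Ugt1a6a, a glucuronosyltransferase, by 2.70 ± 0.31, Lilrb4a by 2.69 ± 0.39, Igsf6 by 2.66 ± 0.53 and Apod, a lipid carrier, by 2.44 ± 0.42 in the authors' deposited table. Rnu3a and Rps16 were also among the 10 largest rises in the authors' deposited table (3.15 ± 0.68 and 2.5 ± 0.41), and both belong to families with near-identical copies. Saa3 passed (FDR = 0.0250) from a level near the floor in cKO saline. Among the largest falls in the authors' deposited table were Fam205a2 (-2.93 ± 0.48), the immediate early gene Egr2 (-1.60 ± 0.26), Tnfrsf25 (-1.58 ± 0.26), the apelin gene Apln (-1.48 ± 0.17), and Dio2, the deiodinase that activates thyroid hormone (-1.25 ± 0.16). Fabp7 (-1.09 ± 0.14), Btbd17 (-1.06 ± 0.23), Robo3 (-1.01 ± 0.21) and Myl4 (-0.94 ± 0.21) followed in the authors' deposited table. Xist, named after its values were seen, had a lower back-calculated level in cKO saline than in cKO LPS. Sex-linked expression thus differed together with treatment in this comparison too.

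Among lists in cKO mice, 9 of 12 complement genes (adjusted p = 1.16e-05), 9 of 16 activated microglia genes (adjusted p = 1.04e-06), 7 of 12 A1-type reactive astrocyte genes (adjusted p = 0.000146), 8 of 13 MHC class I genes (adjusted p = 0.000195) and 8 of 16 endothelial genes (adjusted p = 0.000195) rose in the authors' deposited table; adjusted over the list alone, the counts were 10, 15, 9, 10 and 9. The interferon list passed (adjusted p = 0.00272) with 1 of 16 members past the gene threshold, Ifitm3 at 1.00 ± 0.23. Its median of 0.64 lay close to the 0.67 of controls, while Irf7 had 1.26 ± 0.43 (FDR = 0.0691) in the authors' deposited table. Vim rose by 1.42 ± 0.30, and Gfap had 1.06 ± 0.34 (FDR = 0.0548) in the authors' deposited table. Of 20 homeostatic astrocyte genes, 2 rose (10 changed when adjusted over the list alone), including the potassium channel gene Kcnj10 (0.71 ± 0.08), and 7 fell, including the water channel gene Aqp4 (-0.48 ± 0.10) and S100b (-0.36 ± 0.06), in the authors' deposited table (adjusted p = 0.563). Cholesterol synthesis fell with 5 of 17 genes (adjusted p = 0.0389; 6 when adjusted over the list alone). Homeostatic microglia genes did not pass as a list, with 4 of 14 higher and 3 lower past the threshold (adjusted p = 0.850; 8 when adjusted over the list alone). Of 30 lists, 10 passed upwards and 1 downwards. At a preset correlation of 0.05, the calls of cholesterol synthesis (adjusted p = 0.129), pan-reactive astrocyte genes (adjusted p = 0.111), NF-kB genes (adjusted p = 0.154) and endothelial activation (adjusted p = 0.0581) ended. That of endothelial activation also ended among genes with a mean log2 CPM of at least 1 (adjusted p = 0.0514). With the GC and length trend removed, immediate early genes (adjusted p = 0.0109) and mitochondrially encoded genes (adjusted p = 0.0193) passed as well. Choroid plexus genes lay below 0 in 4 of 4 and did not pass (median -0.29, adjusted p = 0.554). Ttr had -2.83 ± 1.86 (FDR = 0.303) in the authors' deposited table and a back-calculated log2 CPM of 6.8 in cKO saline and 3.6 in cKO LPS.

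**Figure D2:**
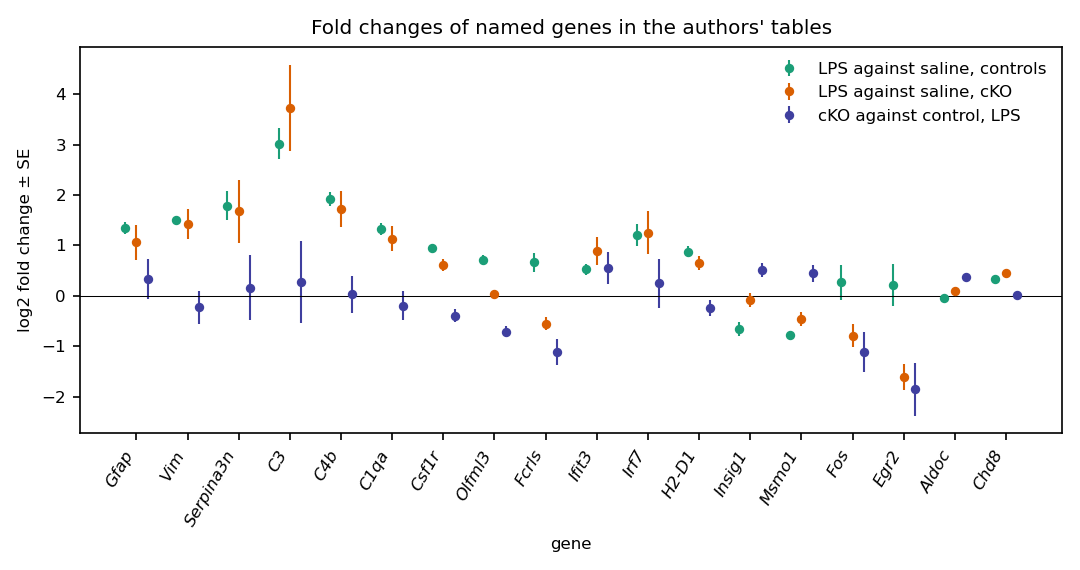
Log2 fold change with its standard error (bars), derived from the authors' F statistics, for 18 genes in the 3 comparisons. Gfap, C3 and C4b lie above 0 for LPS in both genotypes, while Olfml3 is at 0.71 in controls and 0.03 in cKO mice.

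After LPS, few single genes separated cKO from control cortex. In the authors' deposited table for the genotypes, 1 of 13784 genes passed, 0 higher and 1 lower, while 1696 genes had an unadjusted p below 0.05 against 689.2 expected by chance. Sex-linked transcripts stood at different levels in these LPS groups. The back-calculated log2 CPM was 4.2 in control and 5.7 in cKO mice for Ddx3y, 3.2 and 4.2 for Uty, and 7.3 and 6.0 for Xist, which was named after its values were seen.

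As groups, several lists shifted between genotypes after LPS although no member passed over all genes; the table shares its LPS libraries with the tables of LPS in each genotype, so these shifts are not independent of those responses. Adjusted over the list alone, the lists with members that passed were homeostatic astrocyte (4 genes), glucocorticoid response (3), homeostatic microglia, activated microglia, endothelial, pericyte and inhibitory neuron (2 each), and endothelial activation and glial scar matrix (1 each). The activated microglia pair was higher in cKO mice, with Apoe at 0.47 ± 0.08 and Lpl at 0.72 ± 0.13 in the authors' deposited table. The median of that list was -0.12. Plvap of endothelial activation was also higher (1.07 ± 0.19), while 4 of the 5 measured genes were lower. The endothelial pair was split, with Itm2a at -0.42 ± 0.11 and Mfsd2a at 0.85 ± 0.23. Homeostatic microglia genes were lower in cKO mice, with 12 of 14 members below 0 (median -0.32, adjusted p = 5.98e-05), including Olfml3 (-0.71 ± 0.10, FDR = 0.147), Fcrls (-1.12 ± 0.26, FDR = 0.249) and Csf1r, the receptor for a microglial survival factor (-0.39 ± 0.13, FDR = 0.329), in the authors' deposited table. Immediate early genes were lower, with 14 of 14 members below 0 (median -0.55, adjusted p = 5.15e-05), including Egr2 (-1.86 ± 0.52, FDR = 0.291) and Fos (-1.12 ± 0.40, FDR = 0.337) in the authors' deposited table. Glucocorticoid response genes were higher, with 12 of 15 above 0 (median 0.42, adjusted p = 0.000376), including Plin4, which coats lipid droplets (2.54 ± 0.43, FDR = 0.147), and Sgk1 (0.68 ± 0.24, FDR = 0.334) in the authors' deposited table. The untested estimate after saline was already 0.21 for the median of this list and 1.48 for Plin4, and the difference of its LPS responses did not pass (median 0.12, adjusted p = 0.412). Cholesterol synthesis genes were higher, with 14 of 17 above 0 (median 0.23, adjusted p = 0.000957), including Insig1 (0.52 ± 0.14, FDR = 0.282) in the authors' deposited table. The complement (adjusted p = 0.354), interferon (adjusted p = 0.989), A1-type (adjusted p = 0.989) and pan-reactive astrocyte (adjusted p = 0.683) lists did not pass. Of 12 complement genes, however, 9 lay below 0 and 3 above (median -0.15), at percentile 0.71 of random lists matched on mean expression. The complement median for the difference of LPS responses was -0.19, at percentile 0.49, and that list test did not pass either (adjusted p = 0.709). Homeostatic astrocyte genes did not pass as a list either, with 10 of 20 above 0 and 10 below (median 0.00, adjusted p = 0.157). The 4 that passed over the list alone were all higher in cKO mice. They were Aldoc (0.38 ± 0.07, FDR = 0.163), Gjb6 (0.61 ± 0.14, FDR = 0.247), Fgfr3 (0.27 ± 0.07, FDR = 0.278) and Gja1 (0.42 ± 0.11, FDR = 0.282) in the authors' deposited table. Their untested estimates after saline were already 0.24, 0.32, 0.24 and 0.19, and the list's median estimate was 0.13. The saline groups also differed in sex-linked transcripts, which limits every saline estimate given here.

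Lists of neighbouring tissue and other cell types also differed between the genotypes after LPS. Striatal genes were higher in cKO mice in 9 of 9 members (median 0.63, adjusted p = 0.000957), with Ppp1r1b at 0.63 ± 0.20 (FDR = 0.298) in the authors' deposited table, and choroid plexus genes in 4 of 4 (median 0.79, adjusted p = 0.0129). Excitatory neuron genes were lower in 11 of 12 (median -0.14, adjusted p = 0.00989), pericyte and smooth muscle genes in 8 of 10 (median -0.30, adjusted p = 0.0194) and cell cycle genes in 5 of 5 (median -1.11, adjusted p = 0.0129). Endothelial genes were below 0 in 13 of 16 (median -0.20) and did not pass (adjusted p = 0.0679), but passed in the rank-based test (adjusted p = 0.0485) and with the GC and length trend removed (adjusted p = 0.0454). The untested estimates of the median after saline were 0.26 for the striatal, -0.14 for the pericyte and -0.17 for the immediate early gene list. Ribosomal protein genes were higher in 19 of 21 (median 0.10, adjusted p = 5.98e-05) and mitochondrially encoded genes in 12 of 13 (median 0.10, adjusted p = 0.0495). With the GC and length trend removed, the median was -0.05 for excitatory neuron genes (adjusted p = 0.0219), 0.06 for ribosomal protein genes (adjusted p = 0.0156) and 0.17 for mitochondrially encoded genes (adjusted p = 0.00126). The pericyte and mitochondrial calls ended at a preset correlation of 0.05, at an adjusted p = 0.0547 and an adjusted p = 0.131. Fold changes in this comparison also fell with transcript length (Spearman rho across genes -0.204), and genes are not independent replicates.

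The LPS responses of the genotypes were compared directly. Of the 1346 genes changed in controls and the 2681 changed in cKO mice, 725 were changed in both of the authors' deposited tables, 507 up and 218 down, against 97.2 and 38.9 for independent lists of these sizes; no gene was called in opposite directions. With Holm adjustment the order of the counts was the other way, with 72 genes in controls and 14 in cKO mice. Across 13784 genes the fold changes correlated with Pearson r = 0.676 and Spearman rho = 0.630, with an orthogonal slope of cKO on control of 1.06. By the test of the difference, 1 gene passed, with a lower response in cKO mice, while 899 genes had an unadjusted p below 0.05 against 689.2 expected by chance. That test is cautious for genes that respond strongly to LPS, so the count of 899 may be too low. The next genes by p-value were Prom1 (difference -0.78), Pxdn (-0.55), Fcrls (-1.22) and Rmnd1 (-0.59), each with an adjusted p = 0.241. A gene called in 1 genotype only is not thereby shown to differ between them. Lcn2 had a back-calculated log2 CPM of 1.6 in cKO saline against -7.2 in control saline, and its difference did not pass (adjusted p = 0.298). Its LPS response in cKO mice was 1.18 ± 1.30 (FDR = 0.544) in the authors' deposited table, so its level in cKO mice is uncertain. After LPS, cKO against control was -0.02 ± 0.95 (FDR = 0.997).

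**Figure D3:**
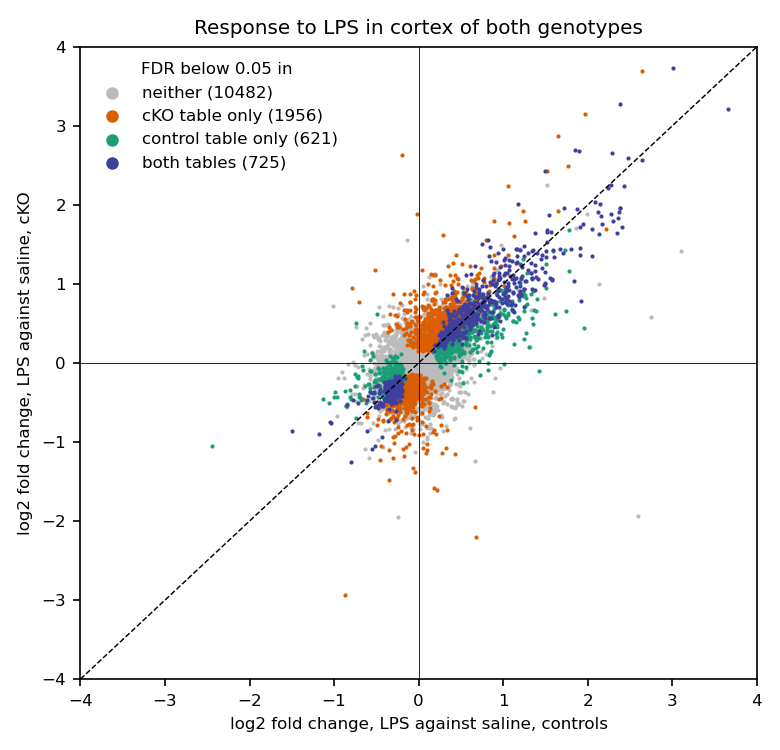
Log2 fold change after LPS in cKO mice (vertical axis) against controls (horizontal axis), 1 point per gene, coloured by the table or tables with an FDR below 0.05; the dashed line marks equal responses, and 8 genes lie outside the axes. The 725 genes called in both tables lie in the upper right and lower left of the plot.

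For 6 of 30 lists the LPS response itself differed between genotypes. It was more negative or less positive in cKO mice for homeostatic microglia (median difference -0.27, adjusted p = 0.000487), immediate early genes (-0.27, adjusted p = 0.00254), cell cycle (-1.09, adjusted p = 0.0220) and excitatory neuron genes (-0.11, adjusted p = 0.0342). It was less negative or more positive for cholesterol synthesis (0.27, adjusted p = 0.000487) and striatal genes (0.35, adjusted p = 0.0232). The excitatory neuron and striatal calls ended at a preset correlation of 0.05 (adjusted p = 0.110 and adjusted p = 0.0671). Endothelial genes were below 0 in 13 of 16 (median -0.15) and did not pass (adjusted p = 0.0861), but passed in the rank-based test (adjusted p = 0.0367). Ribosomal protein genes were above 0 in 18 of 21 (median 0.06, adjusted p = 0.0742). They passed in the rank-based test (adjusted p = 0.0263) and had an adjusted p = 0.879 with the GC and length trend removed. The cell cycle list holds 5 measured genes. Of these, Mki67 and Top2a rose after LPS in controls (1.75 ± 0.32 and 1.43 ± 0.27) and had 0.66 ± 0.43 (FDR = 0.299) and -0.09 ± 0.42 (FDR = 0.892) in cKO mice in the authors' deposited tables. Their own differences did not pass (adjusted p = 0.828 and adjusted p = 0.599). Among genes with a mean log2 CPM of at least 1 in both LPS comparisons, the cell cycle call ended (adjusted p = 0.3345). That minimum leaves out Mki67 and Top2a by their cKO levels (0.48 and 0.83), so the call depended on including them. Of the microglial list, Olfml3 had 0.71 ± 0.09 in controls and 0.03 ± 0.10 in cKO mice in the authors' deposited tables, and its own difference of -0.69 did not pass (adjusted p = 0.298). Of the cholesterol synthesis list, Insig1 had -0.66 ± 0.13 in controls and -0.08 ± 0.14 in cKO mice in the authors' deposited tables, and its own difference of 0.58 did not pass (adjusted p = 0.672).

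After saline, the comparison of cKO with control mice could only be estimated. The median absolute difference computed from the authors' deposited tables was 0.0469 on the log2 scale, with 5th and 95th percentiles of -0.19 and 0.15 over 13784 genes. The median absolute fold change of LPS was 0.136 in controls and 0.158 in cKO mice. No gene was tested in this comparison. The saline groups stood apart in sex-linked transcripts: the back-calculated log2 CPM was -7.2 in control and 5.9 in cKO mice for Ddx3y, -7.3 and 4.8 for Uty, and 7.5 and 4.3 for Xist. These levels argue against the same sex make-up in both saline groups, and sex cannot be separated from genotype in this estimate.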

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

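The tests of the GC and length trend, of microglial RNA and of saline libraries were chosen only after the results were seen; the test of low abundance was not. The gene lists stand here because their LPS response differed between the genotypes by the test of the difference; the standard errors were noticed in the tables.

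The LPS response differed for the lists of homeostatic microglia (median difference -0.27, adjusted p = 0.000487), immediate early genes (-0.27, adjusted p = 0.00254), cell cycle (-1.09, adjusted p = 0.0220), excitatory neuron (-0.11, adjusted p = 0.0342), striatal (0.35, adjusted p = 0.0232) and cholesterol synthesis genes (0.27, adjusted p = 0.000487). At a preset correlation of 0.05 the striatal and excitatory neuron calls ended (adjusted p = 0.0671 and adjusted p = 0.110). The cell cycle call ended among genes with a mean log2 CPM of at least 1 (adjusted p = 0.3345). With the trend of fold change on GC content and transcript length removed, 5 of these 6 lists still passed, which argues against that trend as their whole cause, while the excitatory neuron list did not pass (adjusted p = 0.0955) and kept 46.3% of its median, so for it the trend and a change in neurons cannot be told apart. For the microglial list, a lower share of microglial RNA in cKO LPS cortex would lower activated microglia genes as well. Their median between genotypes was -0.12 with 12 of 16 members below 0. The 2 members that passed over the list alone, Apoe (0.47 ± 0.08) and Lpl (0.72 ± 0.13) in the authors' deposited table, were higher in cKO mice. The list did not pass its test (adjusted p = 0.743), while its median lay at percentile 0.46 of random lists matched on mean expression. These values leave this explanation open. A different state of microglia in cKO mice, unequal dissection towards the striatum for the striatal list, and sex, which the labels used here do not give, may each contribute and were not tested. Y-linked genes were near the floor in control saline and in no other group, so the LPS response of controls also spans a difference in Y-linked expression. Xist had a lower back-calculated level in cKO saline than in cKO LPS. The LPS response of cKO mice, and the difference of the responses, therefore also span differences in sex-linked expression.

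Inflammatory genes had larger standard errors in the tables that hold cKO LPS libraries, and so, to a smaller extent, had cholesterol synthesis and homeostatic astrocyte genes (median ratios of LPS in cKO to LPS in controls 1.30 and 1.22, each at the 100th percentile of matched lists). Over 46 genes of the complement, interferon, A1-type and pan-reactive astrocyte lists, the median ratio of the standard error of LPS in cKO to that of LPS in controls was 1.68, against a median of 1.00 in random lists matched on mean expression, at the 100th percentile, which argues against low abundance. In the table of genotypes after LPS, which holds no saline library, the ratio to the control table was 1.96 against 1.23 in matched lists. Spread among cKO saline libraries cannot raise the errors of that comparison. The control comparison does hold saline libraries, however, so spread common to LPS mice of both genotypes would raise this ratio too. The ratio therefore does not decide whether spread among cKO saline libraries widened the errors of LPS in cKO. Unequal responses among cKO mice given LPS, unequal doses and unequal timing may each widen these errors and cannot be separated without values per library.

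The list of replication-dependent histone genes, chosen after the values were seen, also differed (median difference 0.31, adjusted p = 0.00208), and did not pass with the GC and length trend removed (median 0.20, adjusted p = 0.287). NADH dehydrogenase subunits, likewise chosen after the values were seen, differed by a median of 0.079 (adjusted p = 0.00208), and did not pass with that trend removed (median 0.021, adjusted p = 0.287).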

How the results depend on the processing

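The version with the GC and length trend removed, the standard errors from F and the back-calculated saline levels were chosen after the data were seen; the other alternatives were planned. At an FDR of 0.01, 264 genes passed for LPS in controls and 445 in cKO mice, and at 0.1 the counts were 2557 and 4092. With a minimum fold change of 1.5 they were 498 and 649, and with Holm adjustment 72 and 14, so under Holm more genes passed in controls than in cKO mice. These settings differ in stringency by construction. The correlation of the LPS responses was 0.731 among genes changed in either table and 0.652 among genes with a mean log2 CPM of at least 1; the cause was not tested. List calls in cKO mice went from 11 to 7 at an inter-gene correlation of 0.05, which widens the error of each list by construction. Outside the central 95% of matched random lists lay 20 lists in controls, 17 in cKO mice, 18 between genotypes after LPS and 15 for the difference, against 15, 11, 11 and 6 by the list test; the cause was not tested. With the trend removed, 1007 genes (682 up) and 2090 (1364 up) passed for LPS in controls and cKO mice, and with a minimum mean log2 CPM of 1 the counts were 1265 and 2641. The count of 1 gene for the genotype comparison after LPS and for the difference was the same under each alternative run. No result named by the rule reversed. Of the calls of genes named by the rule, 28 ended with the trend removed and 150 under Holm adjustment. No paired analysis was possible because the tables hold no values per library, although the labels share replicate numbers between groups. For the same reason DESeq2, RLE size factors, fits without a low-count filter, a joint fit of all 4 groups and fits without single replicates were not run. Depth per library is unknown, so no limit of detection is given.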

Other observations

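The 4 lists in this part and the genes named in it were chosen only after their values were seen. In the authors' deposited tables, 15 of 29 replication-dependent histone genes fell after LPS in controls (median -0.72, adjusted p = 8.21e-13) and 5 fell in cKO mice (median -0.43, adjusted p = 0.000358); these genes are near-identical, and most of their transcripts lack poly(A) tails. Of 7 small nucleolar RNA genes, 4 rose in controls (median 1.07, adjusted p = 0.00316) and 7 in cKO mice (median 1.18, adjusted p = 0.000358) in the authors' deposited tables. Of 45 NADH dehydrogenase subunits, 6 fell in controls (median -0.16, adjusted p = 2.14e-07) and 2 in cKO mice (median -0.08, adjusted p = 0.0262) in the authors' deposited tables. The heat shock list did not pass in controls (adjusted p = 0.50) or cKO mice (adjusted p = 0.163).

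Some single genes had low unadjusted p-values between genotypes after LPS without passing the threshold. Agt, which encodes angiotensinogen, had 1.97 ± 0.32 (FDR = 0.147) in the authors' deposited table, where Etnppl had 1.61 ± 0.28 (FDR = 0.147) and Klf15, a transcription factor induced by glucocorticoids, had 0.67 ± 0.10 (FDR = 0.147). The cold-inducible RNA-binding protein gene Cirbp had 0.68 ± 0.13 (FDR = 0.163) and Rbm3, of the same kind, had 0.60 ± 0.20 (FDR = 0.324) in the authors' deposited table. Agt rose after LPS in cKO mice by 1.62 ± 0.25 (FDR = 0.00647) and had 0.29 ± 0.17 (FDR = 0.296) in controls in the authors' deposited tables. The difference did not pass (adjusted p = 0.472). By these fold changes, the untested estimate for Agt after saline was also higher in cKO mice.

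The back-calculated log2 CPM of Xist, which is expressed from the inactive X chromosome, was 7.5 in control saline, 7.3 in control LPS, 4.3 in cKO saline and 6.0 in cKO LPS. Ddx3y and Uty were near the floor in control saline (-7.2 and -7.3) and well above it in every other group, which argues against male mice in control saline. These are group levels, so the number of female and male mice in the other groups was not determined.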
